A study of Homo sapiens with 49 samples.

How the data were processed

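RNA of PA-1 and HEK293 cells was sequenced as total RNA, depleted of ribosomal RNA and with ERCC spike-ins, in stranded libraries, per the labels' protocols. The protocols describe a pair of transfections with small interfering RNA or expression plasmids, together with a GFP or an L1 plasmid, and do not say which library received which plasmid or was run on which of the sequencing instruments. Reads of an L1 plasmid, where one was used, would fall on L1 subfamilies, and this could not be checked per library. Per the submitters' processing notes, bcl2fastq 2.18, STAR and DESeq2 were used, with the builds hg19 and hg38, with no role or order given. How reads of repeated sequence were assigned to subfamilies is not given in the sources used here.

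The deposited values are a signal per L1 subfamily, normalized read counts made by the authors by dividing whole numbers by 1 size factor per library, as their common step shows. With a tolerance of 1e-06 reads, 100% of values came out whole, and 1 value was 0. The whole numbers add to 70368 to 314852 reads per library. They are reads on listed L1 subfamilies, not the depth of the library. The geometric mean of the size factors was 1.01 in the PA-1 and HEK293 knockdown experiments, 1.16 in the MOV10 overexpression set and 1.00 in both other overexpression sets, so levels were compared within these 5 experiments. How the size factors were set, and whether the ERCC spike-ins entered them, is not given in the sources used here. The table lists 76 of the 132 annotated L1 subfamilies, and the other 56 were not analysed here. Copy numbers, lengths and overlap with genes came from the repeat annotation used for counting, whose coordinates fit hg38, set against GENCODE release 29 with bedtools 2.31.1. The TUT7 knockdown columns carry no replicate number and are called libraries a, b and c.

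Libraries were grouped by their labels into 16 groups. Each comparison used limma 3.58.1 in R 4.3.3 (group means, moderated variance with a trend) on log2(value + 1), which understates the change of low subfamilies, for subfamilies with a mean of at least 10 over the fit, which left 74. P-values were two-sided and Benjamini-Hochberg adjusted within a comparison, with a threshold of 0.05. Moderation pooled the variance over the tested subfamilies as if these were independent. They move together, with an estimated correlation of 0.993 for the young list in PA-1 on the deposited scale and 0.870 on the relative one. Very small p-values, above all in fits of few libraries, therefore overstate the evidence. The PA-1 fit held 19 libraries (13 residual degrees of freedom), the HEK293 knockdown fit 12 (8), the overexpression fit 18 (12) and the fit of both lines 31 (21). The overexpression fit shared its spread over sets whose library totals ranged 3.26-fold (MOV10), 1.06-fold (TUT4) and 1.40-fold (TUT7). Its errors and missing calls in the TUT4 and TUT7 sets therefore reflect the MOV10 set too. There were 11 comparisons with control, 3 interactions and 3 differences between lines. Levels relative to all listed L1 were the deposited values rescaled by the median of ratios over the listed subfamilies within the fit. This scale was planned as an alternative and taken as a result of its own after library totals and the counts on the deposited scale had been seen. No count model was run.

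Lists were fixed by name before the data were examined, as were the tests. They were young L1 (L1HS and L1PA2 to L1PA8), older L1PA, L1PB, L1MA, L1MB, L1MC, L1MD, L1ME and other L1M and L1P elements, of which 13 of 15 were tested. HAL1 had 0 listed members. Lists were tested with fry and with camera at a preset correlation of 0.01 and an estimated one. Where no call is given for a list, neither test passed. The text names the 8 young subfamilies, and from the 6 largest rises and 6 largest falls past the threshold with all libraries of a group on 1 side of the control libraries. For interactions and line differences the rule takes 3 each way. On the deposited scale no other subfamily met this rule, and it was applied to the relative scale.

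Within groups, 51 pairs of libraries were compared with a chi-square test of their whole numbers, and 7 pairs had a composition p over 0.05. In 2 of these, both in the TUT7 overexpression set, the level differed by no more than sampling noise too, and each pair was averaged and counted once in means and n, while the fits held all libraries unless averaging is stated. Totals were compared with exact two-sided permutation tests. Tests were run on simulated data in 20 simulations per comparison, with 15 of 74 subfamilies changed. Alternatives were other pseudocounts (0.5 and 10), no filter or a mean of at least 100, other scalings, fits of only the compared groups, a replicate block and leaving out each library. Python 3.11.15, numpy 2.4.6 and scipy 1.17.1 were used for tables and exact tests.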

Results

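RNA from 49 libraries of human cell lines was measured as signal per LINE-1 (L1) subfamily. L1 elements are retrotransposons that copy themselves through RNA, and their subfamilies are named broadly by age. L1HS is the human-specific subfamily and holds the copies that can still move. L1PA2 to L1PA8 are progressively older primate subfamilies, and the L1MA to L1ME groups are older mammalian ones. The cells were PA-1, an embryonic carcinoma line that expresses its own L1 elements, and HEK293, an embryonic kidney line. In PA-1 cells, small interfering RNAs were directed against MOV10, TUT4, TUT7, TUT4 with TUT7, or all 3 proteins. HEK293 cells received the MOV10, TUT4/TUT7 and triple knockdowns, and in separate sets overexpressed MOV10, TUT4 or TUT7. MOV10 is an RNA helicase that restricts L1 mobility, and TUT4 and TUT7 are enzymes that add uridines to the 3' ends of RNAs. Each group had 3 libraries, except the PA-1 TUT4/TUT7 knockdown, which had 4. The levels of MOV10, TUT4 and TUT7 were not analysed here, so the libraries are named as their labels give them. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

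The table listed 76 L1 subfamilies. The L1 reads behind a library, recovered from the step between its values, numbered 70368 to 314852 with a median of 179971, and L1HS itself rested on 281 to 1391 reads. L1HS has 1620 annotated copies in the hg38 repeat annotation, covering 3.41 Mb. Of these, 307 span at least 6000 bp, 45% lie in genes and 2.22% overlap an exon. L1PA2 has 4940 copies over 9.72 Mb, of which 978 span at least 6000 bp, 48.8% lie in genes and 2.59% overlap an exon. L1HS and L1PA2 are near-identical in sequence, so reads could be assigned to either, and their values are uncertain to that extent.

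Total L1 signal differed widely between replicates of several groups. PA-1 control libraries held 193977 ± 13110 normalized counts (SD, n = 3), and the triple knockdown 246962 ± 120931 (SD, n = 3), because its library 1 reached 386571 while the lowest held 174670. HEK293 control knockdown libraries held 121314 ± 57474 (SD, n = 3), with library 1 at 187673 and the lowest at 87349. MOV10 overexpression controls ranged from 68422 to 190233. None of the 11 comparisons of totals with control passed the threshold, with exact two-sided permutation p from 0.2 to 1, and adjusted p of 1 over the 11. The smallest p possible is 0.1 with 3 libraries against 3, 0.0286 for the TUT4/TUT7 knockdown in PA-1 and 0.333 for TUT7 overexpression.

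**Figure D1:**
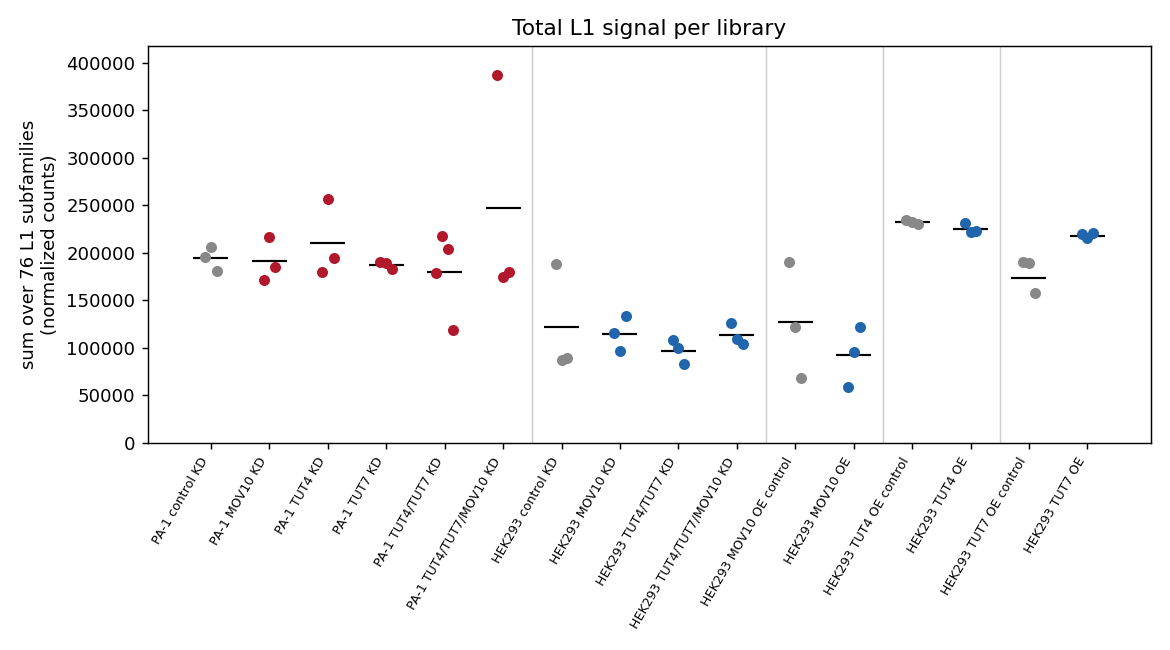
Total L1 signal per library, as the sum of normalized counts over 76 subfamilies, with 1 point per library, a horizontal line at the group mean (alike libraries of the TUT7 overexpression set averaged first), controls in grey, PA-1 in red and HEK293 in blue. Library 1 of the PA-1 triple knockdown, at 386571 normalized counts, lies above all others.

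Because of this spread, every comparison is given on the deposited scale and relative to all listed L1, that is after rescaling each library by the median of its ratios over the listed subfamilies. The second scale shows which subfamilies gained or lost against the other L1 elements and is blind to a change of all L1 together. It was planned as an alternative and taken as a result of its own only after the totals and the counts on the deposited scale had been seen. Over the 11 comparisons with control, the median log2 change on the deposited scale lay between -0.45 in MOV10 overexpression and 0.27 in TUT7 overexpression. On the deposited scale, limma called 0 of 74 tested subfamilies in each of the 17 comparisons at a Benjamini-Hochberg adjusted p of 0.05. At an unadjusted p under 0.05 the count was 2 in the PA-1 triple knockdown, 2 in MOV10 overexpression and 0 in the other 15. In simulations of the PA-1 TUT7 knockdown with 74 subfamilies, a log2 change of 1 was recovered in 65% of cases on the deposited scale and a change of 0.3 in 7%. On the relative scale the recovery there was 100% and 86%. In these simulations subfamilies varied independently apart from a shift of the whole library, and rises and falls were nearly balanced. Subfamilies in the data move together on both scales, so recovery there may differ.

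MOV10 knockdown in PA-1 cells left L1HS at 674 ± 45.0 normalized counts (SD, n = 3), against 609 ± 1.63 in control (SD, n = 3). The log2 change was 0.14 (SE 0.28) with a 95% interval from -0.42 to 0.70 and limma adjusted p = 0.996. L1HS made up 0.355% ± 0.0229 of the listed L1 signal, against 0.315% ± 0.0216 in control (SD, n = 3 each). Its relative log2 change was 0.15 (SE 0.07, limma adjusted p = 0.200). L1PA2, at 1.32% ± 0.0170 against 1.31% ± 0.0224 of the signal, differed by less than the replicate spread. On the relative scale, 8 subfamilies rose and 8 fell. The risers included the old primate elements L1PBa1 (log2 change 0.39, SE 0.12) and L1PBb (0.33, SE 0.10), and the mammalian L1MA1 (0.24, SE 0.05). L1ME2 fell by 0.14 (SE 0.03) and L1MC1 fell by 0.14 (SE 0.04). Of the 8 L1PB members 3 rose and 0 fell, and fry gave the group an up direction (adjusted p = 0.0246). The L1ME list, with 2 falls among 8, had a down direction (fry adjusted p = 0.0477). With an estimated correlation, camera gave adjusted p = 0.333 for L1PB and 0.718 for L1ME. The count of 16 changed subfamilies went to 2, 3 or 4 without MOV10 knockdown replicate 1, 2 or 3, and to 2, 3 or 8 without control replicate 1, 2 or 3.

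TUT4 knockdown in PA-1 cells brought L1HS to 777 ± 174 normalized counts (SD, n = 3), a log2 change of 0.33 (SE 0.28, interval -0.23 to 0.88, limma adjusted p = 0.989). Its share of the L1 signal was 0.368% ± 0.0155 (SD, n = 3), above every control library. The relative log2 change of 0.19 (SE 0.07) passed the limma threshold (adjusted p = 0.0474). Adjusted over the list alone, 0 of the 8 young subfamilies passed, with adjusted p = 0.123 for L1HS. The call on L1HS was lost without control replicate 1 or 2 or any 1 of the TUT4 knockdown libraries, where adjusted p lay between 0.0521 and 0.233. It was also lost under the replicate block. Over 14 alternatives the L1HS change ran from 0.15 to 0.27, with 8 past the threshold. L1PA2 had a relative log2 change of 0.02 (SE 0.09). In all, 12 subfamilies rose and 12 fell. L1PBa1 (0.45, SE 0.12), L1MDb (0.42, SE 0.09) and L1MA1 (0.28, SE 0.05) rose, while L1ME2 fell by 0.18 (SE 0.03) and L1MB4 fell by 0.14 (SE 0.03). The L1PB group had 4 rises among 8 members (fry adjusted p = 0.00543). The L1ME group, among the oldest elements listed, had 4 falls among 8 (fry adjusted p = 0.00277). The L1MB list had 2 falls among 6 (fry adjusted p = 0.0376). With an estimated correlation, camera gave adjusted p = 0.263 for L1PB and L1ME and 0.651 for L1MB. The count of 24 went to 12 or 8 without control replicate 1 or 2, and to 15, 9 or 14 without TUT4 knockdown replicate 1, 2 or 3.

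In the PA-1 TUT7 knockdown, L1HS stood at 728 ± 12.2 normalized counts (SD, n = 3), and the log2 change of 0.26 (SE 0.28, interval -0.30 to 0.81) was not called (limma adjusted p = 0.993). L1HS took 0.389% ± 0.0110 and L1PA2 1.54% ± 0.0298 of the L1 signal (SD, n = 3 each), above every control library in each case. L1HS rose relative to all listed L1 by a log2 change of 0.27 (SE 0.07, limma adjusted p = 0.0144). L1PA2, at 0.19 (SE 0.09, adjusted p = 0.131), did not pass. Of 13 alternatives 2 called L1PA2, the fit of the TUT7 knockdown and control libraries alone (0.19, adjusted p = 1.83e-09) and equal totals (0.23, adjusted p = 0.0438), and adjusted p ran up to 0.285. The smallest of these rests on variance pooled over subfamilies that move together, so its size overstates the evidence. Adjusted over the list alone, 1 of the 8 young subfamilies passed, L1HS (adjusted p = 0.0125). The mean relative change of the young list was 0.04 and its median -0.01. L1PA4 to L1PA8 lay between -0.14 and -0.01. A total of 6 subfamilies rose and 11 fell. L1MDb (0.45, SE 0.09) and L1PB2 (0.27, SE 0.05) rose, L1MC1 fell by 0.23 (SE 0.04) and L1MA4A fell by 0.19 (SE 0.03). The older L1PA list, with 2 rises among 10 members, had fry adjusted p = 0.0378 in the up direction, and the L1ME list, with 3 falls among 8, had fry adjusted p = 0.0378 in the down direction. With an estimated correlation, camera gave adjusted p = 0.655 and 0.747. Without control replicate 1, L1HS had adjusted p = 0.0513, without control replicate 2 0.0767, and without TUT7 knockdown library c 0.0574. The count of 17 went to 7 or 8 without control replicate 1 or 2, and to 8 or 7 without knockdown library a or c. In the fit of the TUT7 knockdown and control libraries alone it rose, as given below.

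In PA-1 cells depleted of both TUT4 and TUT7, L1HS stood at 706 ± 149 normalized counts (SD, n = 4). The log2 change was 0.18 (SE 0.27, interval -0.34 to 0.71, limma adjusted p = 0.994). L1HS took 0.396% ± 0.0173 of the L1 signal and L1PA2 1.56% ± 0.0287 (SD, n = 4 each), above all 3 control libraries. The relative log2 change of L1HS was 0.31 (SE 0.07, limma adjusted p = 0.00473), a fold of 1.24, and that of L1PA2 0.22 (SE 0.08, adjusted p = 0.0932). L1PA2 was called in 2 of 15 alternatives, the fit of these knockdown and control libraries alone (0.23, adjusted p = 5.26e-11) and equal totals (0.24, adjusted p = 0.0315), and adjusted p ran up to 0.232. The smallest value again rests on variance pooled over subfamilies that move together. Adjusted over the list alone, 1 of the 8 young subfamilies passed, with adjusted p = 0.00204 for L1HS and 0.0572 for L1PA2. The L1HS call was lost without control replicate 2 (adjusted p = 0.0632). It was also lost after rescaling by the old elements, at a log2 change of 0.32 (adjusted p = 0.0576). L1MDb (0.42, SE 0.09) and L1PA14 (0.11, SE 0.03) also rose, and L1MB4 fell by 0.15 (SE 0.03), L1MA4A fell by 0.13 (SE 0.03) and L1ME2 fell by 0.12 (SE 0.03). These made 3 rises and 3 falls. Among the lists, the L1ME group had fry adjusted p = 0.0317 in the down direction, with 1 of 8 members called and camera adjusted p = 0.554 with an estimated correlation. Without control replicate 2 the count of changed subfamilies went from 6 to 3, and without TUT4/TUT7 knockdown replicate 4 to 10. It fell further with scaling by old elements and rose further in the fit of these knockdown and control libraries alone, as given below.

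The triple knockdown of TUT4, TUT7 and MOV10 in PA-1 cells gave L1HS at 1009 ± 605 normalized counts (SD, n = 3), with a log2 change of 0.57 (SE 0.28, interval 0.01 to 1.13, limma adjusted p = 0.704). The spread came from library 1, whose young list took 21.3% of the L1 signal against 15.8% on average in the others. L1HS rose relative to all listed L1 by a log2 change of 0.33 (SE 0.07, limma adjusted p = 0.00529) and L1PA2 by 0.33 (SE 0.09, adjusted p = 0.0219). Both lay above every control library in all 3 libraries, and L1PA3, at 0.26 (SE 0.10), did not pass (adjusted p = 0.0923). Adjusted over the list alone, 3 of the 8 young subfamilies passed. The young list as a group had a mean relative change of 0.19 (fry adjusted p = 0.120). The camera adjusted p was 0.0136, in the up direction, for the young list and 0.0439, in the down direction, for L1MA, and 0.483 for both with an estimated correlation. Camera on the deposited scale gave adjusted p = 0.00101 for the young list (up) and 0.0465 for L1MA (down), and 0.982 for both with an estimated correlation. On the relative scale, a fit of the triple knockdown and control libraries alone called no subfamily, with adjusted p = 0.236 for L1HS and 0.303 for L1PA2. Without library 1 of the triple knockdown the young list mean was 0.03 and the L1PA2 change 0.15 (adjusted p = 0.00866). Over 14 alternatives the L1PA2 change ran from 0.15 to 0.42, with 8 past the threshold. L1MDb (0.43, SE 0.09), L1PA10 (0.15, SE 0.05) and L1PA14 (0.12, SE 0.03) rose. L1ME2 fell by 0.14 (SE 0.03), L1MC1 fell by 0.13 (SE 0.04) and L1MB4 fell by 0.13 (SE 0.03). Adjusted p was 0.0621 for L1HS without control replicate 2, and 0.0542, 0.0869 and 0.0655 for L1PA2 without control replicate 1, 2 and 3. The count of 8 went to 5, 2 or 4 without control replicate 1, 2 or 3, and to 5 or 14 without triple knockdown replicate 1 or 2.

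**Figure D2:**
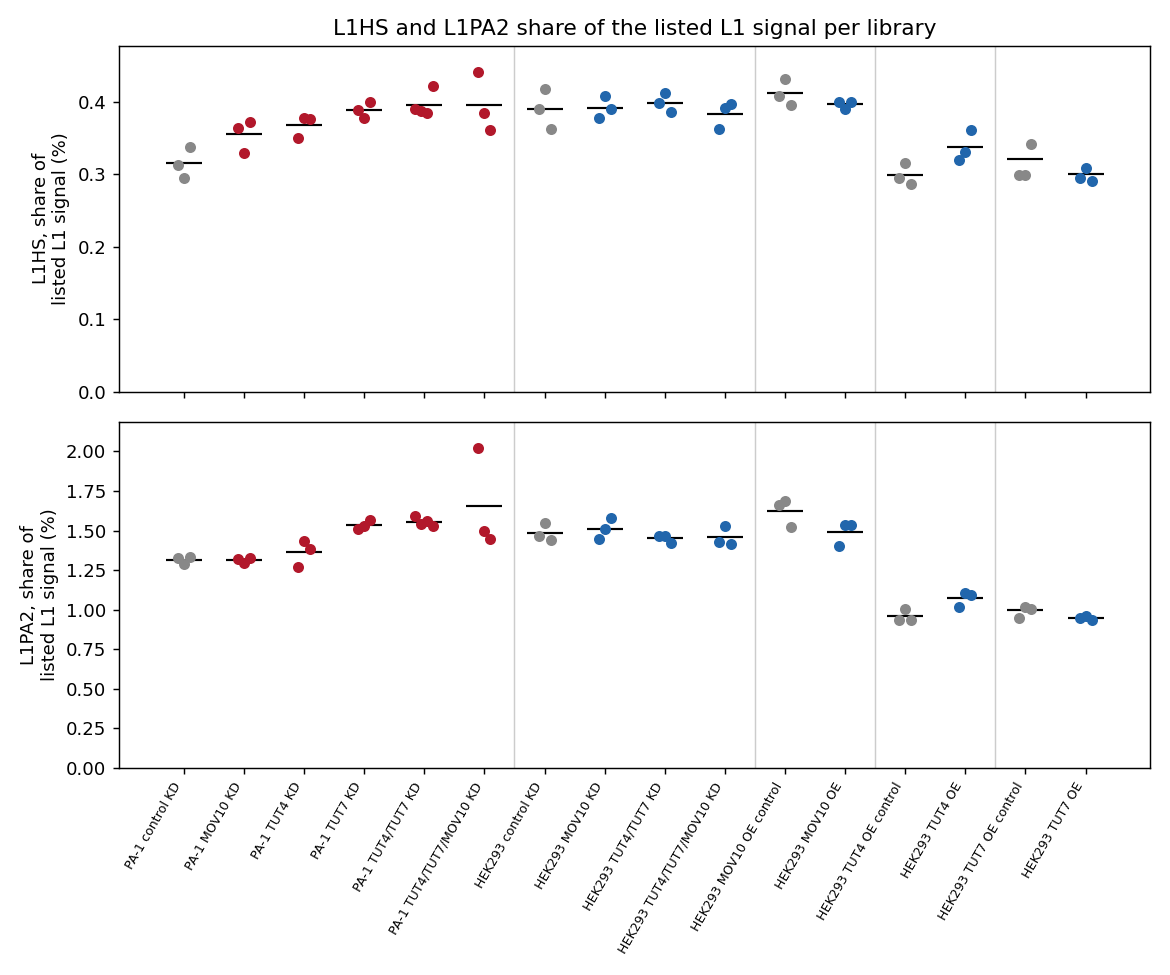
Share of L1HS (top) and L1PA2 (bottom) in the listed L1 signal, in percent, with 1 point per library, a line at the group mean, controls in grey, PA-1 in red and HEK293 in blue. Every PA-1 TUT7 and TUT4/TUT7 knockdown library lies above the 3 PA-1 controls in both panels, with L1PA2 means of 1.54% and 1.56% against 1.31%.

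The same 3 control libraries enter all 5 PA-1 comparisons, so their calls are not independent. L1ME2 was lower and L1MDb higher in all 5, and these 2 subfamilies were the complete overlap. The MOV10 and TUT4 knockdowns shared 7 rises and 6 falls, where independent lists would share 1.30 in each direction. In 100 simulations with no effect the overlap was 0 at most, but calls are then so rare that this says nothing of what shared controls add. At an unadjusted p under 0.05 the pair shared 8 rises and 8 falls, against 0.33 and 0.46 on average in the simulations and 3 at most in either direction. The covariance of their relative changes across subfamilies, which are not independent, was 0.0165, against 0.0033 on average in the simulations, where subfamilies varied independently. This was the highest covariance among the pairs of PA-1 comparisons. The MOV10 and triple knockdowns shared 3 rises and 4 falls, against at most 3 of each in the simulations. Their covariance of 0.0099 lay under the simulated maximum of 0.0120, while that of every other pair lay above its own. The 3 control libraries are too few to be split, so part of the overlap may come from them.

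The interaction of MOV10 with TUT4/TUT7 in PA-1 cells asked whether the triple knockdown differed from the sum of its parts. L1HS had a relative interaction of -0.12 (SE 0.10, limma adjusted p = 0.519) and L1PA2 of 0.13 (SE 0.12, adjusted p = 0.547). On this scale L1MA4A was above the sum by 0.17 (SE 0.05), and L1PBa1 at -0.71 (SE 0.16) and L1MA1 at -0.31 (SE 0.07) were below it. The count of 3 went to 14 without triple knockdown replicate 1 and to 7 without TUT4/TUT7 knockdown replicate 4. For TUT4 with TUT7, L1HS had a relative interaction of -0.16 (SE 0.10, adjusted p = 0.288) and L1PA2 of 0.01 (SE 0.12, adjusted p = 0.950). L1MD3 (0.24, SE 0.06), L1MC1 (0.22, SE 0.05) and L1ME4a (0.20, SE 0.05) were among 4 subfamilies above the sum, and L1MDb (-0.45, SE 0.13) and L1PB2 (-0.35, SE 0.07) were the 2 below it. This count of 6 ranged from 4 to 8 over the left-out libraries. It moved further under other scalings and in the fit of the compared groups alone, as given below.

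In HEK293 cells, L1HS differed between knockdown and control by less than the replicate spread. L1HS stood at 0.390% ± 0.0272 of the L1 signal in control, 0.392% ± 0.0151 after MOV10 knockdown, 0.399% ± 0.0130 after TUT4/TUT7 knockdown and 0.384% ± 0.0183 after the triple knockdown (SD, n = 3 each). The relative log2 changes of L1HS were 0.01, 0.05 and -0.01 (SE 0.07 each), with 95% intervals inside -0.15 to 0.18. Those of L1PA2 were 0.03, -0.02 and -0.02 (SE 0.04 each). On the deposited scale the L1HS changes were 0.01, -0.20 and -0.03 (SE 0.33 each), with limma adjusted p from 0.674 to 1.00. On the relative scale limma called 1 subfamily after MOV10 knockdown, L1MA5, which fell by 0.19 (SE 0.05, adjusted p = 0.0452). It called 0 after TUT4/TUT7 knockdown, 0 after the triple knockdown and 0 in the interaction, where 8, 6 and 6 subfamilies had an unadjusted p under 0.05. For the young list after MOV10 knockdown the mean relative change was 0.05, with fry adjusted p = 0.154. The L1MA5 count went to 0 without control replicate 1 or 3 or MOV10 knockdown replicate 2, and to 2 without MOV10 knockdown replicate 1 or 3.

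Whether a knockdown acted differently in the 2 lines was tested as the difference of the changes, PA-1 minus HEK293. For the triple knockdown, L1HS differed by 0.33 (SE 0.10, limma adjusted p = 0.0343) and L1PA2 by 0.33 (SE 0.10, adjusted p = 0.0343) relative to all listed L1. Without library 1 of the PA-1 triple knockdown these were 0.25 and 0.18, with adjusted p = 0.153 each. Over all alternatives adjusted p ran from 0.00763 to 0.289 for L1HS and from 0.00608 to 0.289 for L1PA2, and the count of 6 called subfamilies ranged from 0 to 14 over the left-out libraries. For TUT4/TUT7 knockdown, L1HS differed by 0.24 (SE 0.09, adjusted p = 0.0892) and L1PA2 by 0.22 (SE 0.10, adjusted p = 0.112). Of 21 alternatives 2 called L1HS (adjusted p from 0.0392 to 0.224) and 2 called L1PA2 (0.00309 to 0.243). For this knockdown 6 other subfamilies were lower in PA-1, among them L1MB4 at -0.24 (SE 0.06), a count that ranged from 1 to 11 over the left-out libraries. MOV10 knockdown gave 0 calls, with 13 at an unadjusted p under 0.05, and 0.10 (SE 0.10) for L1HS. Each line has its own set of libraries, so line and library set cannot be told apart.

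MOV10 overexpression in HEK293 cells gave L1HS at 365 ± 128 normalized counts, against 524 ± 253 in its control (SD, n = 3 each). The log2 change was -0.46 (SE 0.34, interval -1.13 to 0.21, limma adjusted p = 0.345), close to the median of -0.45 over all subfamilies. Relative to all listed L1, the values were -0.03 (SE 0.06) for L1HS and -0.10 (SE 0.05, adjusted p = 0.285) for L1PA2, and 0 subfamilies were called, with 12 at an unadjusted p under 0.05. The young list had a camera adjusted p of 0.0303 in the down direction and L1ME of 0.0131 in the up direction, and 0.476 for both with an estimated correlation. Without control replicate 3 the counts went to 67 on the deposited scale and 35 relative to all listed L1.

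In TUT4 overexpression, L1HS took 0.337% ± 0.0212 of the L1 signal, against 0.299% ± 0.0148 in its control, and L1PA2 1.07% ± 0.0493 against 0.960% ± 0.0405 (SD, n = 3 each), and both lay above every control library. Relative log2 changes were 0.18 (SE 0.06, limma adjusted p = 0.284) and 0.17 (SE 0.05, adjusted p = 0.123). Adjusted over the list alone, 2 of the 8 young subfamilies passed, L1HS (adjusted p = 0.0306) and L1PA2 (adjusted p = 0.0133). Limma called 0 of 74 subfamilies, with 5 at an unadjusted p under 0.05, in a fit that shares its spread with the more variable MOV10 overexpression set. A fit of these 6 libraries alone called 11 on the deposited scale and 6 relative to all listed L1, there with adjusted p = 0.00981 for L1HS and 7.32e-05 for L1PA2. These p-values, too, rest on variance pooled over subfamilies that move together. Without TUT4 overexpression replicate 1, L1PA2 was called (adjusted p = 0.0301). Over its alternatives adjusted p ran from 0.00981 to 0.993 for L1HS and from 7.32e-05 to 0.976 for L1PA2. The camera adjusted p was 0.0423, in the up direction, for the young list and 0.0227, in the down direction, for L1MA, and 0.517 and 0.296 with an estimated correlation.

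TUT7 overexpression came with a higher level of nearly all L1 subfamilies, with a median log2 change of 0.27 and all 3 libraries above all 3 controls for 66 of 74 subfamilies. Replicates 1 and 3 of the overexpression and replicates 1 and 2 of its control differed by no more than sampling noise in composition (chi-square per degree of freedom 0.785, p = 0.915, and 1.14, p = 0.197) and level, and each pair was counted as 1 sample in means. With the pairs averaged, both overexpression samples lay above both controls for 71 subfamilies and below them for 1. Chance gives groups of 2 that do not overlap for 33.3% of independent features, in either direction, and the subfamilies of a library move together. L1HS stood at 655 ± 12.4 normalized counts, against 552 ± 19.7 in control (SD, n = 2 each). The fitted log2 change was 0.23 (SE 0.34, interval -0.45 to 0.90, limma adjusted p = 0.627). This SE comes from a spread shared with the MOV10 overexpression set, whose totals ranged 3.26-fold, against 1.40-fold in the TUT7 set. In a fit of these 6 libraries alone, 62 subfamilies rose and 0 fell, and with the pairs averaged limma called 0, with 26 at an unadjusted p under 0.05. The 62 calls treat subfamilies that move together as independent. Relative to all listed L1, L1HS had a log2 change of -0.04 (SE 0.06), L1PA2 of -0.04 (SE 0.05), and 0 subfamilies were called, with 2 at an unadjusted p under 0.05. The list of other L1M and L1P elements, with 0 of 13 members called, was lower than the rest (camera adjusted p = 0.00391, and 0.0218 with an estimated correlation) in a fit that counted the alike libraries separately, while fry gave adjusted p = 0.0993. With each pair averaged these were 0.00726, 0.0454 and 0.237. The camera adjusted p was 0.00933 for L1MA and 0.0474 for L1ME, both in the up direction, and 0.135 and 0.758 with an estimated correlation. With the pairs averaged L1ME was not called (camera adjusted p = 0.0694). Camera called the other L1M and L1P list on the deposited scale too (adjusted p = 0.00106, and 0.977 with an estimated correlation).

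**Figure D3:**
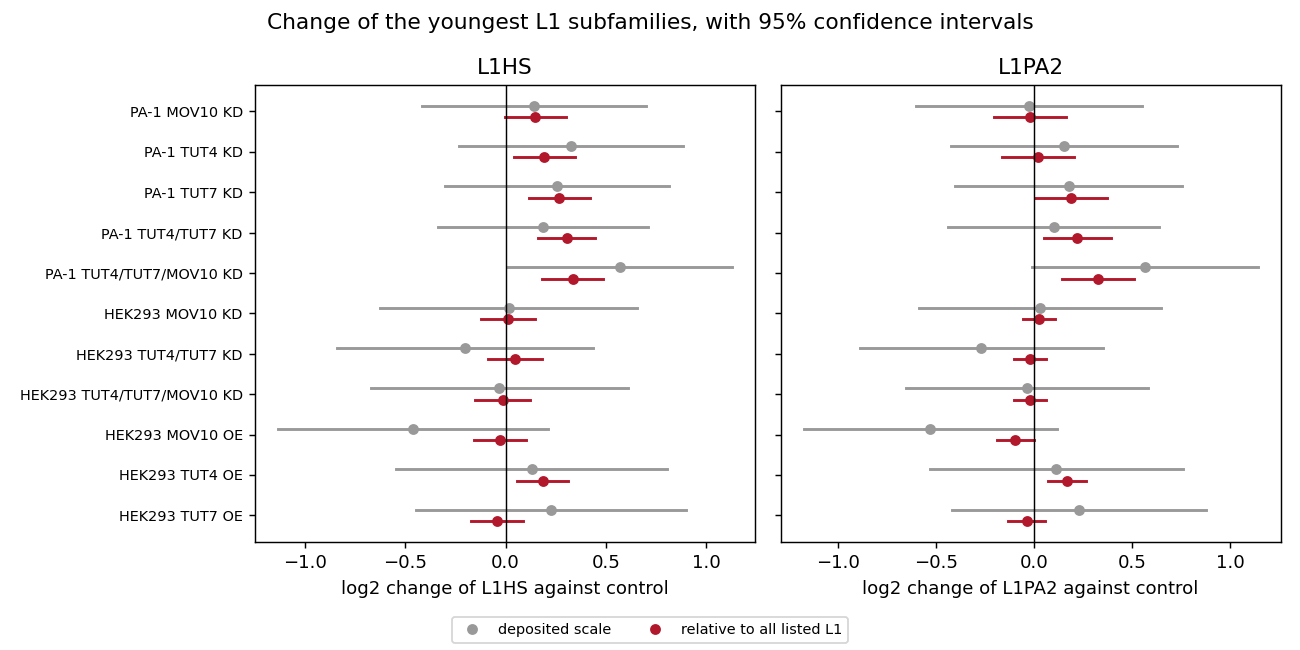
Log2 change of L1HS (left) and L1PA2 (right) against control in the 11 comparisons, as limma estimates with 95% confidence intervals, grey on the deposited scale and red relative to all listed L1. The red L1HS intervals lie above 0 in 4 PA-1 knockdowns and in TUT4 overexpression, while all HEK293 knockdown intervals hold 0.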

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

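The tests on L1HS, on library totals and on TUT7 overexpression in this part were chosen after the results were seen, while the tests between lines and the fits of only the compared groups were planned. In addition, some verdicts below were set to open after their values were seen. For L1HS these were the total signal and low control libraries. For library totals they were a scaling factor in the MOV10 overexpression control and in HEK293 control library 1. The last was repeated libraries in TUT7 overexpression.

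In the PA-1 TUT4/TUT7 knockdown, 1 of 4 libraries stood apart in its L1HS share, at 0.421% against 0.385%, 0.387% and 0.390%, with a gap of 0.867 of the range. Of 17 measures in this group it was the one beyond the limit, and chance gives about 1 in 20. Relative to all listed L1, the TUT4/TUT7 knockdown changed L1MB4 (-0.24), L1MB5 (-0.24) and L1ME4a (-0.22) differently in PA-1 and HEK293 (limma adjusted p = 0.00569, 0.0357 and 0.0292). For the triple knockdown the lines differed in L1HS (0.33), L1PA2 (0.33), L1MC1 (-0.20), L1MB4 (-0.19) and L1MA2 (-0.18), with limma adjusted p = 0.0343 for each. Line and library set are confounded.

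The higher relative level of L1HS in the PA-1 TUT7 and TUT4/TUT7 knockdowns was weighed against differences in the total signal and against low control libraries. With the log2 total as a covariate, L1HS stayed past the threshold in 2 of 2 knockdowns (0.27, limma adjusted p = 0.00280, and 0.32, limma adjusted p = 0.000639). For TUT4/TUT7, whose totals ran from 119056 to 217809, this argues against the total. The TUT7 totals (182701 to 189948) lay within those of the controls (180210 to 206314). The covariate could hardly move that contrast, so it decides nothing there. Against the MOV10 knockdown libraries in place of the controls, the mean L1HS change was 0.14 (SE 0.06), close to 0.144, the bound of 50% of the 0.29 seen against control. Low controls and an effect of TUT7 therefore cannot be told apart, since 0.14 lies within 1 SE of the bound. The MOV10 knockdown is also a treated group, in which L1HS was itself higher than in control, though not called. An effect of that knockdown on L1HS would lower the value as low controls would, so this reference cannot separate them. Reads of an L1 plasmid, which would fall on L1 subfamilies, stay open too, since the protocols do not say which libraries received one. An effect of the knockdown on L1HS may remain, as a hypothesis.

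The libraries with the highest totals in 3 groups were compared with the others of their group. In library 1 of the PA-1 triple knockdown the composition differed from both others (lowest chi-square per degree of freedom 43.0, against 0.938 between the others and at most 6.57 in the groups not weighed here), which argues against 1 scaling factor as the whole cause. Its fold over the others was higher for subfamilies with more annotated length per control signal (Spearman's rho 0.58 across 74 subfamilies, which are not independent, permutation p = 1e-05, the smallest they can give), and 26.1% of the excess was in young L1, which hold 29.0% of the annotated length and 15.8% of the signal of the others. This is what reads spread over copies by length, such as genomic DNA, may give. A rise of L1 RNA that is larger in young L1 may give it too, so the 2 cannot be told apart. The young list had the lowest signal per annotated Mb of all lists in PA-1 controls (291, against 396 for older L1PA to 967 for L1ME). In HEK293 control library 1 the tables argue against length (rho -0.0013, p = 0.991), while a single factor stays open, since its composition differed by no more (4.35 and 6.11, against 1.43 between the others) than that of replicates elsewhere and its young share of 22.0% lay between the 22.4% and 21.7% of the others, and in MOV10 overexpression control library 1 both stay open (3.92 against library 2 and 30.1 against library 3, which itself differed from library 2 by 17.6, and rho 0.48, p = 3e-05).

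In TUT7 overexpression, the fit of its own libraries called 62 subfamilies, all higher. Relative to all listed L1 it called 1, as a single scaling factor per library would give, and a change of all L1 together would give that too. With the alike libraries averaged it called 0, with 26 at an unadjusted p under 0.05, while the median log2 change went from 0.27 (SE 0.10) to 0.31 (SE 0.17), so the calls ended with the larger error. Repeated libraries and a general rise of L1 cannot be told apart here, with only 2 samples left per group.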

How the results depend on the processing

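Scaling relative to all listed L1 as a result of its own, the alternatives run on top of it and the averaging of alike libraries, also in list tests, were chosen after seeing the data. No value changed sign between its own fit and an alternative where either was past the threshold, while others did. Between alternatives this did not hold, as in the young list of TUT7 overexpression below. On the deposited scale 36, 33 and 30 of 136 named values changed sign when rescaled by median of ratios, totals or old elements, and in at least 1 of these so did the young list means of -0.020 (PA-1 MOV10), -0.049 (PA-1 TUT4/TUT7) and 0.26 (TUT7 overexpression). For fry, the threshold in this part is on its unadjusted p. The planned count model was not run, since the recovered reads could be judged on 76 subfamilies only. The chi-square tests and the read counts given here rest on the same recovered reads. The cause was not tested for any change below. Pseudocounts of 0.5 or 10 kept all 197 named relative values on their side of the threshold. Depth limits L1HS to 281 to 1391 reads.

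On the deposited scale (0 calls in all 17), rescaling by median of ratios gave 16, 24, 17, 6 and 8 calls in PA-1 MOV10, TUT4, TUT7, TUT4/TUT7 and triple knockdown, 1 in HEK293 MOV10 knockdown, 3 and 6 in the PA-1 interactions and 6 and 6 in the TUT4/TUT7 and triple line differences, with young list means of 0.072 (PA-1 TUT4/TUT7), 0.048 (HEK293 MOV10, past the unadjusted threshold of fry) and -0.0077 (TUT7 overexpression). Equal totals gave 9, 16, 16, 10 and 8 in PA-1, 1 and 2 in HEK293 MOV10 and TUT4/TUT7 knockdown, 4 and 10 in the PA-1 interactions and 1, 8 and 2 in the line differences, with young means of 0.0084 (PA-1 MOV10), 0.095 (PA-1 TUT4/TUT7) and -0.036 (TUT7 overexpression). Scaling by old elements gave 10, 12, 15, 1 and 5 in PA-1, 2 in HEK293 TUT4/TUT7 and 4 and 2 in the PA-1 interactions, with young means of 0.053 (PA-1 MOV10), 0.085 (PA-1 TUT4/TUT7), 0.11 (HEK293 MOV10, past the threshold of fry) and -0.039 (TUT7 overexpression). No filter gave 1 each in PA-1 TUT4, HEK293 MOV10 and the HEK293 interaction. Only the compared groups gave 7 in PA-1 TUT7, 11 in TUT4 overexpression (also with alike libraries averaged) and 62 in TUT7 overexpression (young mean 0.26, past the threshold of fry).

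Relative to all listed L1, equal totals gave 9 in PA-1 MOV10 (young mean 0.0084), 10 in PA-1 TUT4/TUT7, 2 in HEK293 TUT4/TUT7, 10 in the TUT4 with TUT7 interaction and 1 and 2 in the MOV10 and triple line differences, and a young mean of 0.045 in HEK293 MOV10, not past the unadjusted threshold of fry, which 0.048 as fitted had passed while missing the adjusted one. Scaling by old elements gave 10 (young mean 0.053), 12, 1 and 5 in PA-1 MOV10, TUT4, TUT4/TUT7 and triple knockdown, 0 and 2 in HEK293 MOV10 and TUT4/TUT7, 2 in the TUT4 with TUT7 interaction and 0 and 0 in the TUT4/TUT7 and triple line differences. No filter gave 2 in HEK293 MOV10 and 1 in the HEK293 interaction. A mean of at least 100 gave 0 in HEK293 MOV10, and it and a pseudocount of 10 gave 1 in the MOV10 line difference. Only the compared groups gave 42, 21 and 0 in PA-1 TUT7 (young mean 0.047, past the threshold of fry), TUT4/TUT7 (0.080, past it) and triple knockdown, 0 in HEK293 MOV10 (0.049, not past it), 6 in TUT4 overexpression (6 with alike libraries averaged), 1 in TUT7 overexpression (2 with alike libraries averaged), 1 and 19 in the PA-1 interactions and 5, 13 and 0 in the line differences. With an estimated correlation, camera calls went from 3 to 0 on the deposited and from 13 to 1 on the relative scale.

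Replicate numbers showed no clear pairing of the samples. Of same-numbered pairs, 10 of 30 in PA-1, 5 of 18 in HEK293 knockdown and 17 of 45 in overexpression had a correlation over 0.1. This correlation across subfamilies cannot see a shift of a whole library, and pairs with unlike numbers were not compared. A pairing is therefore not excluded. With the replicate block, which leaves out the unnumbered TUT7 knockdown, the relative counts were 5 in the PA-1 triple knockdown, 1 in TUT4 overexpression and 0 in the triple line difference, and L1HS in PA-1 TUT4 (0.19) and L1PA2 in the PA-1 triple knockdown (0.32) were among 17 named relative values whose call was lost. Under the block the young mean was 0.15 in PA-1 TUT4/TUT7 on the deposited scale, and -0.019 and -0.031, both past the threshold of fry, in HEK293 TUT4/TUT7 and triple knockdown on the relative one.

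Leaving out single libraries, relative counts ranged from 2 to 8 in PA-1 MOV10, 8 to 20 in TUT4, 7 to 15 in TUT7, 3 to 10 in TUT4/TUT7 and 2 to 14 in the triple knockdown, 0 to 2 in HEK293 MOV10, 0 to 1 in HEK293 TUT4/TUT7, 0 to 35 in MOV10 overexpression (0 to 67 deposited), 0 to 1 in TUT4 overexpression, 2 to 14 in the PA-1 and 0 to 2 in the HEK293 MOV10 interaction, and 0 to 1, 1 to 11 and 0 to 14 in the line differences. Relative young means ranged from -0.020 to 0.071 in PA-1 TUT4, 0.031 to 0.27 in the triple knockdown, 0.039 to 0.061 in HEK293 MOV10, -0.10 to -0.029 in MOV10 overexpression and -0.019 to 0.0079 in TUT7 overexpression. Deposited young means ranged from -0.12 to 0.060 in PA-1 MOV10, -0.035 to 0.31 in TUT4, -0.012 to 0.071 in TUT7, -0.15 to 0.15 in TUT4/TUT7 and -0.085 to 0.69 in the triple knockdown, -0.13 to 0.41, -0.46 to 0.091 and -0.23 to 0.31 in HEK293 MOV10, TUT4/TUT7 and triple knockdown, -0.94 to -0.11 in MOV10 and -0.013 to 0.028 in TUT4 overexpression. Where an arm was left with few libraries, these were assumed to vary like the other groups.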

Other observations

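The tests in this part were chosen after the results were seen, except the interactions and comparisons themselves.

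All other lists, L1MB, L1MC and L1ME among them, gave a higher mean signal per annotated length than the young list in each of the 5 control groups. How reads of repeated sequence were assigned is not given, and copies within genes may be read with those genes. Signal per length is therefore no measure of how far the elements themselves were transcribed. In PA-1 controls L1HS gave 179 ± 0.478 normalized counts per Mb, L1PA2 262 ± 13.9 and the young list 291 ± 20.1 (SD, n = 3), against 694 ± 44.2 for L1MC and 967 ± 71.4 for L1ME. In HEK293 knockdown controls the young list gave 256 ± 121 and L1ME 481 ± 225 (SD, n = 3). The HEK293 control sets differed among themselves, with L1ME at 1066 ± 23.8 per Mb and young L1 at 385 ± 8.75 in the TUT4 overexpression control (SD, n = 3). Whether the sets were normalized together is not given in the sources used here.

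A hypothesis was that younger subfamilies gain more relative signal when TUT4 or TUT7 is depleted in PA-1 cells. The prediction, set before the values of rho were seen, was at least 3 of 4 knockdowns past the adjusted threshold, and 0 passed. Across the 8 youngest subfamilies, which are not independent, rho between age rank and relative change was below 0 in all 4, at -0.40 in TUT4, -0.81 in TUT7, -0.62 in TUT4/TUT7 and -0.69 in the triple knockdown. The lowest exact permutation p was 0.0218, in TUT7 (adjusted p = 0.120 over 11 comparisons). Missing the threshold does not exclude a trend in the predicted direction, and the 4 share their controls, so the hypothesis was set to open after these values were seen. In TUT4 overexpression rho was -0.98 (exact permutation p = 0.000397, adjusted p = 0.00437), so the same direction arose without depletion. In the PA-1 MOV10 knockdown rho was -0.24. In HEK293 cells it was 0.48, -0.31 and 0.45 in the MOV10, TUT4/TUT7 and triple knockdowns, and -0.05 and 0.48 in MOV10 and TUT7 overexpression. A negative rho is therefore not particular to depletion of TUT4 or TUT7.

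With the MOV10 knockdown libraries as reference, limma called 0 subfamilies relative to all listed L1 in TUT4 knockdown (5 at an unadjusted p under 0.05), 3 in TUT7, 0 in TUT4/TUT7 (10 at an unadjusted p under 0.05) and 3 in the triple knockdown.

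Other splits of the same libraries were counted. With 3 libraries against 3 the 10 splits are too few for a share under 0.05. On the relative scale the real split gave 16 calls in PA-1 MOV10 knockdown, 24 in TUT4, 17 in TUT7 and 8 in the triple knockdown, and the highest other split 0 in each, so 1 of 10 splits gave as many. HEK293 MOV10 knockdown gave 1 against 1 in the highest other split (2 of 10 as large). HEK293 TUT4/TUT7 knockdown gave 0 against 1, the triple 0 against 3, MOV10 overexpression 0 against 34, and TUT4 and TUT7 overexpression 0 against 0, with 10 of 10 as large. For the PA-1 TUT4/TUT7 knockdown 1 of 35 splits gave as many, 6 against 2. This share, under 0.05, is the smallest that the design can give and was not adjusted over the 17 comparisons. For the PA-1 interaction of TUT4 with TUT7 1 of 100 drawn splits gave as many, 6 against 3. Splits for interactions shuffled all groups, and those for line differences all groups of a line. They also break up differences between single groups, so they cannot exclude chance for an interaction or a line difference. The share was also under 0.05 for the PA-1 interaction of MOV10 with TUT4/TUT7 (2 of 100, 3 against 4) and the line differences of TUT4/TUT7 (2 of 100, 6 against 6) and the triple knockdown (3 of 100, 6 against 10), but another split gave as many calls or more, so chance is not excluded for these. The count of the triple line difference also went to 0 under the replicate block and without single libraries. Chance was not excluded for the HEK293 interaction (100 of 100, 0 against 11) or the line difference of MOV10 (100 of 100, 0 against 13).

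On the deposited scale the real count was 0 everywhere and all splits gave as many, 10 of 10, 35 of 35 and 100 of 100. The highest other split was 0 in all 5 PA-1 comparisons, HEK293 TUT4/TUT7 knockdown, TUT4 and TUT7 overexpression, the TUT4 with TUT7 interaction and the TUT4/TUT7 line difference. It was 71 in HEK293 MOV10 knockdown, 68 in the HEK293 triple knockdown, 74 in MOV10 overexpression, 36 in the PA-1 MOV10 interaction, 73 in the HEK293 interaction, 62 in the MOV10 line difference and 72 in that of the triple knockdown. Subfamilies move together on this scale, so a split that happens to order the libraries by total can call most of them at once. Such counts therefore show no further structure of the libraries.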
